A study of Rattus norvegicus with 9 samples.

How the data were processed

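Small RNA libraries from rat left ventricle were compared between 3 groups of 3 libraries each. WKY are normotensive Wistar-Kyoto rats given saline, SHR are spontaneously hypertensive rats given saline, and ZSHLF are spontaneously hypertensive rats given the Chinese herbal Zishen Huoluo formula. All animals were male and 16 weeks old, and treatment lasted 4 weeks, per the labels. The design text names 5 WKY and 10 SHR rats. Nothing in the labels says that each library came from a separate rat, so p-values measure the spread between these libraries, part of which may be technical.

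Total RNA was extracted with TRI Reagent, adapters were ligated to both ends, and the products were reverse transcribed, amplified and size-selected, per the labels' protocols. The same protocols state that RNA from different groups was mixed before the libraries were built. Each library is nevertheless labelled with a single group, and what was mixed is not explained. The group names below are those of the labels, and if RNA was pooled across groups, none of the contrasts below compares the groups it names. The deposited values are raw read counts per mature miRNA and hairpin, per the file header, with no normalization by the authors. The aligner, the counting program, the miRBase release and the genome build are not given in the sources used here. Coordinates are printed as the table gives them. No miRNA in the table had a mean count below 4.56 or a highest count below 11, so rarer miRNAs were not analysed here, and 8 empty lines were skipped.

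The table listed 412 lines for 365 mature miRNAs, because a mature miRNA made from several hairpins is repeated once per hairpin. Of 42 such miRNAs, 19 had counts that differed between their lines, by a median of 0.93% and by at most 88.3%. The line with the highest mean count was kept for each mature miRNA, a choice made after the table was seen. Near-identical mature miRNAs, such as miR-1b and miR-1-3p or miR-133a-3p and miR-133b-3p, can share reads, and their separate values are uncertain.

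Libraries held 5502316 to 9905730 counted reads. A count of 3, taken as the floor of detection, equals 0.287 to 0.75 CPM (reads scaled to a common library size, here with the TMM factor) depending on the library. Floors and counting intervals (95%, exact Poisson) cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Every pair of replicates differed far beyond sampling noise (chi-square per degree of freedom 119 to 1761), so none was counted as a library deposited more than once.

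The tests used edgeR 4.0.16 in R 4.3.3. Counts were filtered with filterByExpr at a minimum count of 10, which kept 348 miRNAs and left out 17, and scaled by TMM. All 9 libraries entered a single quasi-likelihood fit with group as the only term, and 3 contrasts were tested: SHR against WKY, ZSHLF against SHR and ZSHLF against WKY. A miRNA was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. CPM values are scaled by TMM, and log2 CPM values used a prior count of 2. The script was tested on simulated counts for SHR against WKY with 348 miRNAs, 100 of them changed so that most of those tested stayed unchanged. Over 20 simulations, 65.6% of 2-fold changes and 97.2% of 4-fold changes were recovered, 3.64% of calls were false, and data with no change gave 0.4 calls per fit. These recovery rates hold for 100 changed miRNAs. With fewer changed, the adjusted threshold is harder to pass, so they do not show that an uncalled miRNA changed less than 2-fold.

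A set of 21 miRNA lists (families, genomic clusters, heart miRNAs and markers of other cell types) was fixed before the data were examined, as were the contrasts, the tests, the rule for named miRNAs and the alternatives, except those said below to be added. The 19 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with adjustment over 57 list and contrast pairs. Camera with an estimated correlation and fry were alternatives. Where a miRNA is said to pass when adjusted over the list alone, the adjustment covered only that list in that contrast. It did not cover the other lists and contrasts, and such a pass was not counted as a call. Named were, for each contrast, all called miRNAs up to 24, then the lowest unadjusted p up to 20 in all, given as not passing; of each list, the called members or otherwise up to 3 of the most abundant; up to 10 miRNAs past an unadjusted p of 0.05 in opposite directions in SHR against WKY and ZSHLF against SHR; and the 10 most abundant miRNAs. Others are named as chosen after their values were seen.

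The alternatives were DESeq2 1.42.0 size factors, total-count scaling, no count filter, a mean of at least 50 counts, the replicate number as a block, summed lines per mature miRNA, DESeq2's Wald test, limma 3.58.1 voom, a fit of only the 2 groups compared, the 3 most abundant miRNAs left out, and each library left out in turn. Limma voom with library quality weights, all hairpin lines kept and a correction for GC content were added after the data were seen. A test of deposited normalized values was not run, because the table holds counts. The correlation of SHR against WKY with ZSHLF against SHR was set beside 100 simulations of unchanged groups that share the SHR libraries.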

Results

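MicroRNAs, short RNAs that repress messenger RNAs, were sequenced from the left ventricle of WKY, SHR and ZSHLF rats in 9 libraries, 3 per group. Total counts were 9382416, 7851113 and 9905730 in WKY replicates 1 to 3, 9312853, 5502316 and 6175703 in SHR, and 8404285, 9583236 and 6338544 in ZSHLF. Of 365 mature miRNAs in the table, 360 to 365 had reads in each library. miR-1b, a near-identical relative of the muscle miRNA miR-1, was the most abundant in every library and took 22.1% ± 5.64 (SD, n = 3) of counts in WKY, 26.6% ± 4.95 in SHR and 25.9% ± 1.64 in ZSHLF. miR-143-3p, known from smooth muscle, followed at 8.53% ± 1.09, 8.45% ± 1.70 and 8.74% ± 0.351. The other 8 of the 10 most abundant miRNAs were miR-1-3p, miR-30a-5p, miR-126a-3p, miR-133a-3p, miR-148a-3p, miR-99a-5p, miR-26a-5p and miR-378a-3p, and together the 10 took 64.4% to 78.0% of a library's counts.

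SHR replicate 2 stood apart from the other 8 libraries. Its score on the main component of log2 CPM was 12.56, against -5.36 to 1.52 elsewhere, and its deviations from the mean of the other libraries had an SD of 0.80 (log2) against 0.39 to 0.56. In this library miR-133b-3p lay 2.22 below the other libraries' mean (log2 deviation -2.22), miR-133a-3p was at -1.85, miR-208a-3p at -1.47 and miR-29c-3p at -1.45, while miR-184 was at 2.25, miR-10b-5p at 1.67 and miR-34c-5p at 1.48. Of these, miR-133b-3p and miR-208a-3p were named after their values were seen. The 3 WKY libraries lay between 3.62 and 4.28 on the other component and the 3 ZSHLF libraries between -6.14 and -3.22.

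**Figure D1:**
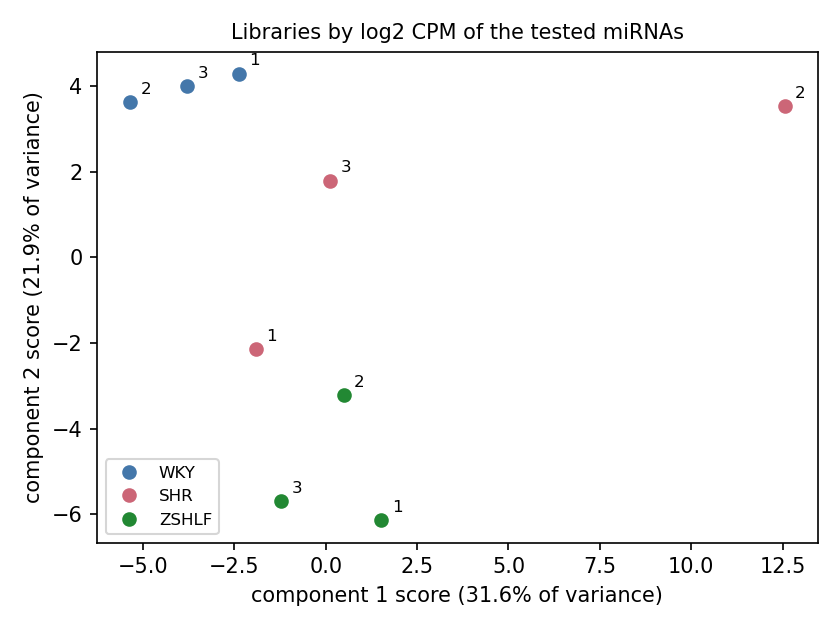
Scores of the 9 libraries on the first components of log2 CPM over 348 miRNAs, with the share of variance on each axis, colours for the groups and numbers for the replicates. SHR replicate 2 lies at 12.56 on component 1, and the WKY and ZSHLF libraries do not overlap on component 2.

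The comparison of SHR with WKY asks which ventricular miRNAs differ between the hypertensive and the normotensive strain on saline. No miRNA passed the test, and the nearest was miR-190b-5p, at 8.83 ± 0.793 CPM (SD, n = 3) in SHR and 3.47 ± 0.648 in WKY (log2 change 1.35, SE 0.25, edgeR adjusted p = 0.0699). The miR-34 and miR-449 family, whose miR-34 members are known targets of p53, was shifted upward as a list, with a median log2 change of 1.27 over 5 tested members, 4 of them higher in SHR (camera adjusted p = 0.0174; adjusted p = 0.5 with an estimated correlation). miR-34c-5p was 2.47-fold (log2 1.30, SE 0.32) and miR-34b-5p 2.42-fold in SHR, whereas miR-34a-5p, the most abundant member, was at -0.04 (log2, SE 0.16). Adjusted over the list alone, 3 members passed: miR-34c-5p, miR-34b-5p and miR-34b-3p, the last named after its values were seen. miR-34b-3p rested on few reads, 32, 32 and 12 in SHR replicates 1 to 3 against 11, 21 and 13 in WKY. Its rise was thus carried by SHR replicates 1 and 2. The list no longer passed without WKY replicate 1 (median 1.27, camera adjusted p = 0.056) or without SHR replicate 1 (median 1.38, 0.131), and its median was 0.86 without SHR replicate 2.

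The highest unadjusted ranks in SHR against WKY also held all of the miR-183/96/182 cluster, a sensory and epithelial gene cluster transcribed together, with log2 changes of 1.47 for miR-96-5p (SE 0.36), 1.34 for miR-182 (SE 0.33) and 1.23 for miR-183-5p (SE 0.33), each with an edgeR adjusted p of 0.123. These 3 passed when adjusted over the list alone, although the epithelial list as a whole had a median of -0.11 (camera adjusted p = 0.37), and its median and mean (0.29) differed in sign. Without WKY replicate 2 that median was 0.27. miR-208b-3p, which sits in the gene of the slow myosin heavy chain, was at 316 ± 123 CPM in SHR and 594 ± 61.7 in WKY (log2 -0.91, SE 0.26, edgeR adjusted p = 0.135). Its SHR mean was lowered by replicate 2, with 717 reads against 3442 and 2759 in SHR replicates 1 and 3. miR-204-5p had a log2 change of 1.17, miR-378b of 0.77, miR-378a-3p of 0.92, miR-148a-3p of 0.87 and miR-184 of 1.88, the last 0.82 without SHR replicate 2. The lower ones included miR-3542 at -1.57, miR-3102 at -1.70, miR-193b-3p at -0.93, miR-301a-5p at -0.85, miR-326-3p at -0.68 and miR-181c-3p at -0.60. Of the miR-132 and miR-212 cluster, miR-132-5p (log2 0.88, SE 0.29) passed when adjusted over the list alone, and all 3 tested members were higher (median 0.75, camera adjusted p = 0.143).

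Markers of blood and other tissue were measured in the same contrast. Erythroid markers had a median of 0.99, with all 4 tested members higher in SHR (camera adjusted p = 0.105), miR-144-3p at 1.11 (SE 0.49) and miR-451-5p at 0.87 (SE 0.51). The erythroid list passed without WKY replicate 2 (median 1.39, camera adjusted p = 0.00455), and its median was 0.39 without SHR replicate 2, which held the highest erythroid level of the 9 libraries (mean log2 CPM 6.99). Markers of liver, kidney and gut had a median of 0.59 (camera adjusted p = 0.392), and of 0.27 to 0.63 with a library left out. Among them miR-122-5p, a liver miRNA, was at 1.10 (SE 1.23), and at 2.68 without WKY replicate 1 or 0.42 without SHR replicate 3.

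By edgeR's quasi-likelihood test, 0 of 348 miRNAs passed in SHR against WKY, 56 had an unadjusted p under 0.05 (33 higher, 23 lower) where chance gives 17.4, DESeq2 called 15 and limma voom 0. The groups did not overlap for 54 miRNAs, 15.5% against 10% by chance. Without SHR replicate 2, 3 miRNAs passed: miR-190b-5p higher, and miR-328a-3p and miR-351-5p lower, the last 2 named after their values were seen. Among the DESeq2 calls was miR-148a-3p, at a log2 change of 0.87, whose partner arm miR-148a-5p, named after its values were seen, was at -0.05 (SE 0.22).

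The comparison of ZSHLF with SHR asks what the herbal formula did within the hypertensive strain. The miRNAs of the imprinted Dlk1-Dio3 cluster on chromosome 6, whose 20 tested members lie between positions 133699509 and 133893771 of the table's unnamed build, were lower in ZSHLF for 20 of 20 members, with a median log2 change of -0.92 (camera adjusted p = 1.18e-11; adjusted p = 0.419 with an estimated correlation). miR-382-5p was at 0.758 ± 0.265 CPM in ZSHLF and 2.52 ± 0.871 in SHR (log2 -1.67, SE 0.42), miR-434-5p had a log2 change of -1.59 (SE 0.45), miR-369-3p of -1.40, miR-379-5p of -0.94 (SE 0.32) and miR-127-3p of -0.84 (SE 0.31). No member passed over all miRNAs, and miR-382-5p and miR-434-5p passed when adjusted over the list alone. The cluster's mean log2 CPM was 2.44 in SHR replicate 3, 1.93 in replicate 2 and 1.44 in replicate 1, against 0.71 to 1.36 in ZSHLF, and without SHR replicate 3 its median change was -0.69. The miR-382-5p level in ZSHLF rested on 6, 9 and 3 reads, near the detection floor of 0.344 to 0.503 CPM in these libraries.

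Epithelial markers were higher in ZSHLF than in SHR for 8 of 10 tested members, with a median log2 change of 0.88 (camera adjusted p = 9.49e-05; adjusted p = 0.419 with an estimated correlation). miR-200c-3p, a miRNA that holds cells in an epithelial state, was at 40.1 ± 1.72 CPM in ZSHLF and 19.5 ± 2.29 in SHR (log2 1.04, SE 0.28), and miR-200b-3p had a log2 change of 1.62 (SE 0.53). The miR-183/96/182 cluster was at 0.88 to 1.07. Over all miRNAs 0 members passed, and 6 passed when adjusted over the list alone: those 5 and miR-200a-3p, named after its values were seen. Neural markers were lower for 6 of 6 members, with a median of -0.46 (camera adjusted p = 0.0478; adjusted p = 0.635 with an estimated correlation), miR-9a-5p at -0.75 (SE 0.31) and miR-128-3p at -0.44 (SE 0.17). The neural call was lost without each library other than ZSHLF replicate 2 (camera adjusted p = 0.056 to 0.435), with medians of -0.16 without SHR replicate 3 and -0.28 without ZSHLF replicate 3, and under DESeq2 and total-count scaling (0.0502 and 0.0589), with no filter (0.144), with summed lines (0.0503) and without the 3 most abundant miRNAs (0.153).

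**Figure D2:**
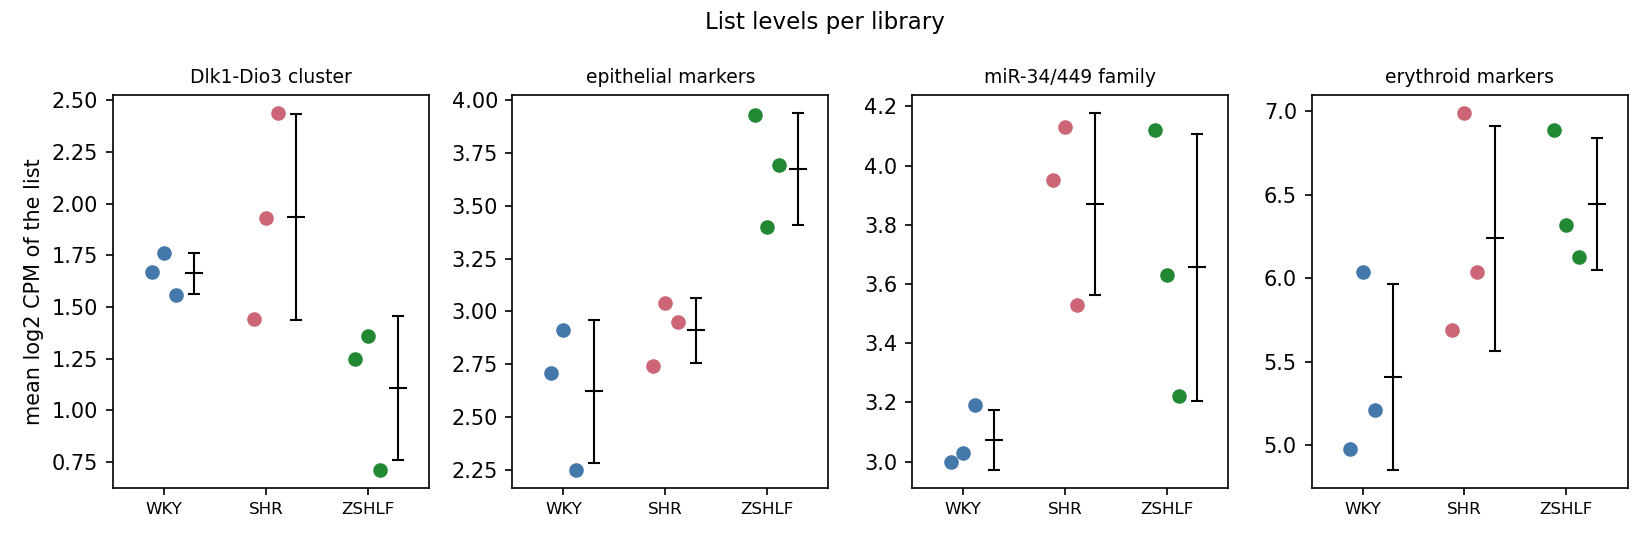
Mean log2 CPM of 4 miRNA lists in each library, with the group mean and SD (n = 3) as black bars beside the points; the vertical axes do not start at 0. The Dlk1-Dio3 level is 0.71 to 1.36 in ZSHLF and 1.44 to 2.44 in SHR, and the epithelial level is 3.40 to 3.93 in ZSHLF and 2.74 to 3.04 in SHR.

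Among single miRNAs in ZSHLF against SHR, none passed. miR-133a-3p, a heart and skeletal muscle miRNA known to restrain growth of heart muscle cells, was at 60390 ± 11000 CPM in ZSHLF and 31410 ± 17000 in SHR (log2 0.94, SE 0.37, edgeR adjusted p = 0.368). Its level in SHR replicate 2 was 12330 CPM, against 44940 and 36960 in the other SHR libraries. miR-19b-3p was at 1.04, miR-16-5p at 0.48, and miR-31a-5p at 1.32. In SHR replicate 2 miR-19b-3p had a log2 deviation of -1.45 from the mean of the other libraries, so part of its change rests on that library. Without ZSHLF replicate 3 the change of miR-31a-5p was 0.63. miR-31a-3p had 5, 1 and 0 reads in the SHR libraries (0.252 ± 0.253 CPM) and was at 1.60 ± 0.789 CPM in ZSHLF. On the lower side were miR-676 at -0.80, miR-674-3p at -1.60, miR-10b-5p at -1.30, miR-99a-5p at -0.58, miR-325-5p at -1.07 and miR-204-5p at -0.99 (log2 changes). Without SHR replicate 2, miR-674-3p was at -0.68 and miR-10b-5p at -0.65.

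By edgeR's quasi-likelihood test, 0 of 348 miRNAs passed in ZSHLF against SHR, with a smallest adjusted p of 0.304. An unadjusted p under 0.05 was found for 36 (16 higher, 20 lower) where chance gives 17.4, DESeq2 and limma voom called 0 each, and the groups did not overlap for 51 (14.7%, 10% by chance). Without SHR replicate 1, 2 passed, miR-10b-5p and miR-676, both lower, and without SHR replicate 2, 0 passed.

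In ZSHLF against WKY strain and treatment differ together, and 7 miRNAs passed, 6 higher and 1 lower. The miR-183/96/182 cluster rose: miR-96-5p from 2.64 ± 0.754 CPM in WKY to 15.5 ± 5.92 in ZSHLF (SD, n = 3; log2 2.54, SE 0.36), miR-182 from 8.52 ± 0.823 to 40.0 ± 14.4 (log2 2.23, SE 0.33) and miR-183-5p from 3.51 ± 0.617 to 15.3 ± 4.88 (log2 2.11, SE 0.33), each with an edgeR adjusted p of 0.00571. The table places their hairpins on the minus strand of chromosome 4, miR-182 at 57459773 to 57459834, miR-96 at 57463366 to 57463471 and miR-183 at 57463569 to 57463678. The mature sequences given with the counts are UUUGGCACUAGCACAUUUUUGCU for miR-96-5p, UUUGGCAAUGGUAGAACUCACACCG for miR-182 and UAUGGCACUGGUAGAAUUCACU for miR-183-5p. SHR lay between, at 7.24 ± 1.94, 21.9 ± 7.75 and 8.29 ± 2.64 CPM.

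miR-146b-5p, a brake on inflammatory signalling encoded on chromosome 1 at 266089488 to 266089575, rose from 337 ± 63.5 to 669 ± 86.9 CPM (log2 0.99, SE 0.19, edgeR adjusted p = 0.019). Its other arm, miR-146b-3p, had a log2 change of 1.18 (SE 0.28) without passing (adjusted p = 0.0623). miR-190b-5p (chromosome 2, 189421137 to 189421214) rose 2.56-fold (adjusted p = 0.0154), to 8.90 ± 1.77 CPM in ZSHLF beside 8.83 ± 0.793 in SHR. miR-452-5p rose 2.78-fold, from 32.4 ± 7.03 to 90.1 ± 31.4 CPM (adjusted p = 0.0411). miR-3102 (chromosome 1, 165921184 to 165921320) fell, on very few reads: 13, 18 and 19 in WKY and 2, 3 and 0 in ZSHLF, a depth-adjusted ratio of 0.135 with a 95% counting interval of 0.042 to 0.336 (adjusted p = 0.0212).

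**Figure D3:**
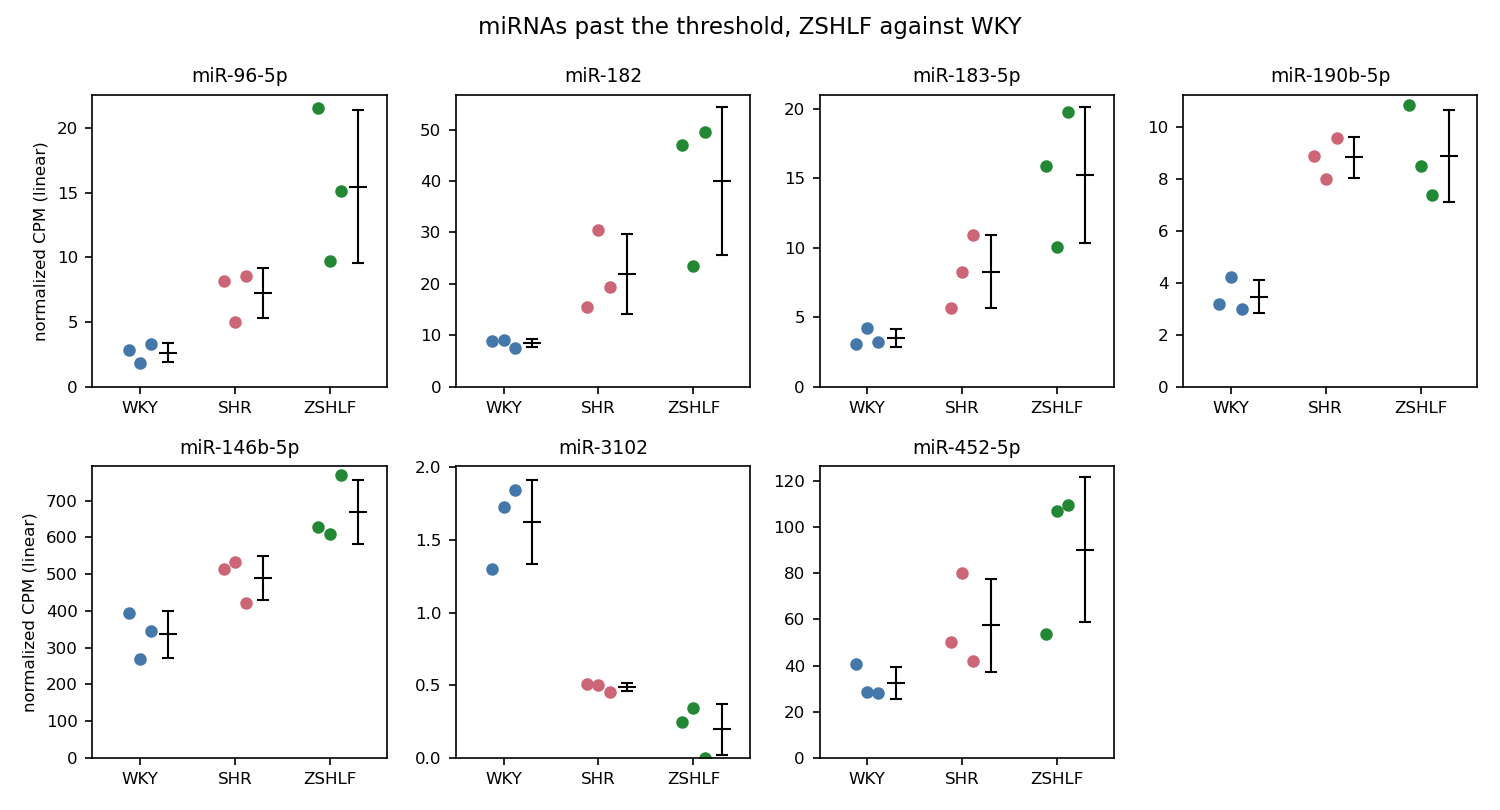
Normalized CPM, on linear axes from 0, of the 7 miRNAs past the threshold in ZSHLF against WKY, one point per library in each group, with the group mean and SD (n = 3) as black bars. Every ZSHLF library lies above every WKY library for 6 of them, such as miR-182 at 23.4 to 49.5 against 7.58 to 9.10 CPM, and below for miR-3102.

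As lists, epithelial markers were higher in ZSHLF than in WKY (8 of 10, median 0.74, camera adjusted p = 9.83e-06; adjusted p = 0.419 with an estimated correlation). Without WKY replicate 3 this median was 0.39, and without WKY replicate 2 it was 1.2. The 3 members that rose were the miR-183/96/182 cluster, and the same 3 passed when adjusted over the list alone. Erythroid markers were higher for 4 of 4 members (median 1.01, camera adjusted p = 0.0314; adjusted p = 0.635 with an estimated correlation), with miR-144-3p at 1.85 (SE 0.48), miR-451-5p at 1.55 (SE 0.52) and miR-486 at 0.46 (SE 0.18), and these 3 passed when adjusted over the list alone. The erythroid call was lost without WKY replicate 1 (median 0.82, camera adjusted p = 0.0991), WKY replicate 3 (median 1.01, 0.0666) or ZSHLF replicate 1 (median 0.75, 0.0623), its median was 1.60 without WKY replicate 2, and miR-144-3p was at 1.17 without ZSHLF replicate 1. Leukocyte markers had a median of 0.24 over 10 members, 8 of them higher (camera adjusted p = 0.0478; adjusted p = 0.419 with an estimated correlation). Of these miR-146b-5p alone rose, 3 passed when adjusted over the list alone, and with total-count scaling the list did not pass (camera adjusted p = 0.105), its median moving to -0.05 with the shift of -0.29 that this scaling gave all miRNAs. The leukocyte call was lost without each library other than WKY replicate 2 (medians 0.18 to 0.31, camera adjusted p = 0.0541 to 0.112), and with DESeq2 size factors (0.0502), no filter (0.0576), a mean of at least 50 counts (0.174), summed lines (0.0503) and the GC correction (0.0824). The Dlk1-Dio3 cluster was lower for 19 of 20 members (median -0.53, camera adjusted p = 0.00138; adjusted p = 0.652 with an estimated correlation), miR-127-3p at -0.60 (SE 0.31) and miR-411-5p at -0.53 (SE 0.23), and it did not pass among miRNAs with a mean of at least 50 counts (median -0.63, adjusted p = 0.164).

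Other miRNAs at the top of the ranking without passing were miR-542-3p (log2 1.04), miR-378a-3p (1.01), miR-378b (0.71), miR-488-3p (0.77), miR-30a-5p (0.73) and miR-223-3p (0.69) on the higher side, and miR-208b-3p (-0.94), miR-365-3p (-0.99), miR-328a-3p (-1.15), let-7c-1-3p (-0.80) and miR-99a-5p (-0.62) on the lower side. miR-208b-3p was at 310 ± 26.6 CPM in ZSHLF, beside 316 ± 123 in SHR and 594 ± 61.7 in WKY. The SHR mean was lowered by SHR replicate 2, so the closeness of SHR and ZSHLF rests partly on that library.

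The count of 7 depended on single libraries. Without SHR replicate 2, which is outside this contrast but enters the common spread, 27 miRNAs passed (18 higher, 9 lower), and all 7 were among them. A fit of only the WKY and ZSHLF libraries called 39 (20 higher, 19 lower), all 7 included, DESeq2 called 21 and limma voom 6. Leaving out WKY replicate 1 gave 0 (adjusted p = 0.0595 to 0.0775 for the 7, with miR-96-5p at a log2 change of 2.59), WKY replicate 3 gave 1 (miR-96-5p), ZSHLF replicate 2 gave 3, and WKY replicate 2, ZSHLF replicate 1 and ZSHLF replicate 3 gave 4 each. Total-count scaling called 3 higher and 2 lower against 6 and 1. It moved the median log2 change of all miRNAs by -0.29 in this contrast, by -0.26 in SHR against WKY and by -0.03 in ZSHLF against SHR. The unadjusted p was under 0.05 for 48 miRNAs, where chance gives 17.4, and the groups did not overlap for 117 (33.6%, 10% by chance).

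Whether the formula moved miRNAs back toward the WKY level was examined across all 348 miRNAs. The miRNAs past an unadjusted p of 0.05 in opposite directions were 4: miR-204-5p (log2 1.17 in SHR against WKY, -0.99 in ZSHLF against SHR), miR-382-5p (1.21 and -1.67), miR-148a-3p (0.87 and -0.72) and miR-24-1-5p (0.45 and -0.58). Simulated unchanged groups gave 3.94 on average and independent lists 2.95. In the same direction in both steps were another 4, miR-182, miR-183-5p, miR-96-5p and miR-146b-5p, where the simulations gave 0.04. However, miR-182, miR-183-5p and miR-96-5p belong to a single cluster transcribed together, so the 4 are not independent events. Each miRNA was drawn independently in the simulations, which therefore do not show how often linked miRNAs reach such a count together. miR-146b-5p had log2 changes of 0.54 and 0.45.

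Across miRNAs, which are not independent replicates, the log2 changes of SHR against WKY and ZSHLF against SHR correlated at r = -0.33 (Spearman -0.441). Unchanged groups sharing the SHR libraries gave an r of -0.508 (SD 0.0602) and a Spearman value of -0.485 (SD 0.0467) over 100 simulations. The covariance was -0.0859 against a simulated -0.0699 (SD 0.013), and 12 of 100 simulations reached a value as low. All 100 simulations gave an r at or below the observed one, and 84 gave a Spearman value as low. Neither correlation was more negative than sharing the SHR libraries gives without any change. The share of miRNAs with opposite signs was 70.4%, against a simulated 66.9% (SD 2.4), and 7 of 100 simulations reached it. The simulations gave every library the same spread for a miRNA, whereas SHR replicate 2 deviated more (SD 0.80 against at most 0.56). What more scatter in a shared SHR library does to these values was not simulated, so the covariance and this share cannot be judged by them. The 3 SHR libraries are too few to split with 2 in each part.

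The lists of heart miRNAs and the remaining families passed in none of the 3 contrasts. Medians are given for SHR against WKY, ZSHLF against SHR and ZSHLF against WKY in that order. Muscle-enriched miRNAs were at -0.19, 0.02 and -0.13, with miR-1-3p at 0.62, -0.18 and 0.44 and miR-499-5p at -0.21, -0.18 and -0.39, and of these miRNAs miR-208b-3p passed in ZSHLF against WKY when adjusted over the list alone. miRNAs reported raised in the stressed heart were at 0.11, 0.06 and 0.11, and miR-21-5p, the best known of them, at 0.11 (SE 0.17), 0.21 and 0.31. miRNAs reported to limit hypertrophy or fibrosis were at -0.14, 0.16 and 0.08. The miR-29 family, which targets collagens, was at -0.20, 0.26 and 0.03, and without SHR replicate 2 at 0.01 in SHR against WKY and -0.06 in ZSHLF against SHR. The miR-30 family was at 0.05, 0.13 and 0.16. Without SHR replicate 2 it passed in ZSHLF against SHR (median 0.34, camera adjusted p = 0.00829) and was at -0.19 in SHR against WKY, and without SHR replicate 1 or 3 it was at -0.03 in ZSHLF against SHR (0.602 and 0.701). The let-7 family was at -0.23, 0.09 and -0.07, and without SHR replicate 2 at -0.07 in SHR against WKY. The family of miR-15, miR-16, miR-195, miR-322 and miR-497 was at -0.06, 0.19 and 0.14, the miR-17-92 clusters at -0.03, 0.10 and 0.04, and the clusters of miR-23, miR-27 and miR-24 at 0.02, 0.05 and 0.04. The miR-132 and miR-212 cluster was at -0.20 and 0.52 in the ZSHLF contrasts, the former 0.05 without ZSHLF replicate 2. Several other medians near 0 also changed sign with a library left out, such as that of the muscle-enriched list without SHR replicate 2 (0.06 in SHR against WKY and -0.17 in ZSHLF against SHR).

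Smooth muscle markers had medians of 0.01, 0.08 and 0.15, fibroblast and mesenchymal markers of 0.11, 0 and 0.08, and the liver, kidney and gut markers of 0.20 and 0.30 in the ZSHLF contrasts. The value of 0.20, in ZSHLF against SHR, was -0.47 without ZSHLF replicate 1, which held 1086 reads of miR-122-5p, and 0.64 without ZSHLF replicate 3. Leukocyte markers were at 0.20 and 0.19, and neural markers at 0.03, in the contrasts not given above; the neural median in ZSHLF against WKY was -0.46 (camera adjusted p = 0.12; 0.0454 without ZSHLF replicate 2 to 0.525 without ZSHLF replicate 3), where miR-128-3p and miR-129-5p, the latter named after its values were seen, passed when adjusted over the list alone. Erythroid markers were at 0.44 and the miR-34 and miR-449 family at -0.36 in ZSHLF against SHR, the latter at 0.71 in ZSHLF against WKY (camera adjusted p = 0.143; 0.0451 without ZSHLF replicate 3 to 0.39 without ZSHLF replicate 1). The Dlk1-Dio3 median in SHR against WKY was 0.30 (camera adjusted p = 0.143). It was 0.58 without SHR replicate 1 (0.0259) and -0.03 without SHR replicate 3 (0.948), so its direction rested on SHR replicate 3. Lists with fewer than 3 tested members were not tested: the endothelial miR-126a-3p was at 0.20, -0.30 and -0.10, its other arm miR-126a-5p at -0.33, 0.34 and 0.01, and the hypoxia-induced miR-210-3p at -0.50, 0.26 and -0.24. Total-count scaling moved all miRNAs together by the shifts given above, so list medians just above 0 turned negative with it, and these sign changes were not read as changes of a list relative to the other miRNAs. This was so in SHR against WKY for the stressed-heart, miR-30, miR-23, smooth muscle, leukocyte, fibroblast and neural lists. In ZSHLF against WKY it was so for the stressed-heart, antihypertrophic, miR-29, miR-30, miR-15, miR-17-92, miR-23, smooth muscle, leukocyte and fibroblast lists, and in ZSHLF against SHR for the muscle-enriched list (-0.04). The mean had the opposite sign to the median for the miR-30 list (-0.01) and the miR-15 list (0.01) in SHR against WKY, for the miR-23 list in ZSHLF against SHR (-0.01), and for the muscle-enriched (0.04), miR-29 (-0.04) and fibroblast (-0.01) lists in ZSHLF against WKY. Camera's direction was down against a positive median for the miR-30 and neural lists in SHR against WKY, for the miR-23 list and the liver, kidney and gut list in ZSHLF against SHR, and for the miR-29 list in ZSHLF against WKY. It was up against a negative median for the epithelial list in SHR against WKY.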

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

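The tests in this part were chosen after the result was seen, except the splits of the libraries and the thinning of the Dlk1-Dio3 comparison to equal depth. Groups of 3 libraries are too small to be examined for single outlying values.

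Among the 17 miRNAs below the count filter, which entered no comparison, 8 had a library above every WKY library by exact 95% Poisson intervals of their CPM. The intervals were not adjusted for the number of miRNAs and libraries compared. ZSHLF replicate 2 held 192 reads of miR-743b-3p, 173 of miR-741-3p, 132 of miR-743a-3p, 55 of miR-881-3p, 44 of miR-471-5p and 25 of miR-471-3p, all on chromosome X, where no WKY library had more than 4 reads of any. No other library of any group, ZSHLF included, had more than 12. miR-21-3p had 29 reads in ZSHLF replicate 1, against at most 11 in WKY (lower bound 2.39 CPM, highest WKY upper bound 1.97). miR-329-5p had 16 reads in SHR replicate 3, against at most 7 in WKY, and passed only barely (1.39 against 1.38 CPM).

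SHR replicate 2 stood apart from the other 8 libraries, with an SD of its log2 deviations of 0.80 against at most 0.56. Its low depth is argued against: with all libraries thinned to 5502316 reads the SD was still 0.78, and the highest of the others 0.54. GC content is argued against by an SD of 0.79 after its trend was removed. A different share of another cell type would move both arms of a hairpin together, but over 60 hairpins with both arms measured the correlation of the arms in this library was -0.04 (95% interval -0.29 to 0.22; 0.05 to 0.78 in the other libraries), with miR-30e-5p at -1.15 and miR-30e-3p at 0.93, for example, both named after their values were seen. So a different cell type share alone does not account for its deviations. Such a difference beneath them stays open, because scatter between arms lowers this correlation, and the SD of the arms was 0.78 here against 0.22 to 0.39 elsewhere. Also open are RNA condition or library preparation, for which the labels give no batch, and differences between animals that act on single arms. A technical origin is a hypothesis that no test here addressed directly.

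The miR-183/96/182 cluster was higher in ZSHLF than in WKY. Scaling is argued against, since the lowest of the 3 log2 changes was 1.82 under total-count or DESeq2 scaling, and GC content likewise, at 2.07 after correction. More epithelial cells would raise the other epithelial markers too, but the median of the 7 others was 0.60 (SD 0.53), against 2.11 for the lowest of the cluster, and in SHR against WKY it was -0.36 while the cluster's median was 1.34. Some of these others were uneven in WKY replicates 1 to 3, such as miR-200b-3p (113, 168 and 32 reads) and miR-200a-3p (114, 155 and 30). How far the medians of these 7 rest on single WKY libraries was not tested. The median of the whole epithelial list in SHR against WKY moved from -0.11 to 0.27 without WKY replicate 2. The others also had a higher level in WKY, at a median of 9.72 CPM against 3.51 for the cluster. An equal gain in CPM would therefore raise them by a smaller log2 change. So the lower medians of the others do not exclude more epithelial cells. In ZSHLF against SHR the other 7 had a median of 0.82 (SD 0.72) beside 0.88 for the lowest of the cluster, so more epithelial cells may account for that step and stay open there as well. Strain and treatment differ together in ZSHLF against WKY, a cell type rich in this cluster alone was not tested, and all 3 calls were lost without WKY replicate 1 (adjusted p = 0.0595 each), although the log2 changes stayed at 2.03 to 2.59.

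The Dlk1-Dio3 cluster was lower in ZSHLF than in SHR. Depth is argued against by a median log2 change of -0.95 with all libraries at equal depth (-1.06 to -0.83 over 20 thinnings), and GC content by -0.94 after correction. A lower share of fibroblasts is argued against by the fibroblast and mesenchymal markers, whose median change was 0 (SD 0.56). Of the 6 tested, 3 were higher and 3 lower. The lowest, miR-10b-5p at -1.30, fell by more than the cluster's median, and was at -0.65 without SHR replicate 2. The neural markers, which were lower too at a median of -0.46, leave a loss of nerve tissue open. The 20 members share a locus, so they may be a single event counted 20 times, and the median was -0.69 without SHR replicate 3 and -1.21 without SHR replicate 1.

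Other splits of the libraries tested whether an arbitrary division of them gives such counts. For each single contrast there are 10 splits of 6 libraries, too few for a share under 0.05: the real counts were 0, 0 and 7, the highest of the other splits gave 0, 0 and 0, and 10, 10 and 1 of the 10 splits gave as many. Where the real count is 0, every split gives as many whatever the data, so the contrasts without a call could show nothing here. Over all 3 contrasts, 100 of 280 possible splits of the 9 libraries into 3 groups of 3 were drawn, the real one included. Of the 100, 3 gave 7 or more calls, counting the real one (highest other 7). That share is under 0.05 and makes chance less likely. Since arbitrary splits matched the real count and not all splits were drawn, chance is not excluded. For the 8 list and contrast pairs, 10 of 100 splits gave as many or more (highest other 10), so chance cannot be excluded for the number of list calls.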

How the results depend on the processing

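The quality weights, the GC correction and the use of all hairpin lines were chosen after seeing the data, and the cause of a change was not tested except where fewer libraries or miRNAs make it. For SHR against WKY (0 calls), a mean of at least 50 counts, quality weights and the GC correction gave 1 each, DESeq2's Wald test 15, and leaving out a library 0 to 3. For ZSHLF against SHR (0 calls), leaving out a library gave 0 to 2, and no other setting gave a call. For ZSHLF against WKY (7 calls), DESeq2's Wald test gave 21, a fit of the 2 groups 39, quality weights 52, and leaving out a library 0 to 27. Replicate numbers do not pair the libraries: same-numbered libraries correlated at -0.27 to 0.17, 3 of 9 pairs exceeded 0.1 and 3 of 9 libraries correlated best with their own number. With the replicate number as a block 3 were called in ZSHLF against WKY and 0 in the other 2 contrasts. The block also gave 8 list pairs, with erythroid markers in SHR against WKY gained (adjusted p = 0.0431) and leukocyte markers in ZSHLF against WKY lost (0.0703). The correlation of -0.33 was 0.14 with no filter, reversed, and -0.44 to -0.06 with a library left out, where unchanged groups were not simulated, so these values cannot be read as a change in the relation. The 8 list pairs became 5 with a mean of at least 50 counts, 0 with an estimated correlation, 0 with fry and 4 to 8 with a library left out. Of single miRNA values under the alternatives, 4528 stayed on their side of the threshold, 85 gained a call and 41 lost one. Of list values, 1021 stayed, 6 gained and 49 lost a call, and 1 reversed: the median of the leukocyte markers in ZSHLF against WKY, -0.05 with total-count scaling, a move no larger than the shift of -0.29 that this scaling gave all miRNAs, so the list did not reverse relative to the others. Of the miRNA values 0 reversed with a call. A test of deposited normalized values was not run. Depth limits the rarest: miR-3102 had at most 3 reads per ZSHLF library.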

Other observations

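Both arms of miR-378a and of the muscle miRNA miR-133a were compared, a comparison chosen after the values were seen; reads of both can be shared with the near-identical miR-378b and miR-133b. miR-378a-3p, made within a gene of mitochondrial metabolism, was at 14930 ± 631 CPM (SD, n = 3) in WKY, 28220 ± 13600 in SHR and 29970 ± 5130 in ZSHLF, while miR-378a-5p was at 152 ± 12.3, 175 ± 39.4 and 214 ± 9.78. miR-133a-3p was at 35160 ± 2230, 31410 ± 17000 and 60390 ± 11000 CPM, while miR-133a-5p was at 916 ± 63.2, 828 ± 214 and 828 ± 93.8. In SHR replicate 2, the library that stood apart, the log2 deviations were 1.07 for miR-378a-3p and -0.51 for miR-378a-5p. They were -1.85 for miR-133a-3p and -0.61 for miR-133a-5p. The SHR means of these arms, and their wide SDs, therefore rest partly on that library. None of these differences between the groups passed in the fit of all 9 libraries. In ZSHLF against WKY, however, miR-378a-3p, miR-378a-5p and miR-133a-3p were called without SHR replicate 2, in the fit of only those 2 groups and by limma voom with quality weights, and DESeq2's Wald test called miR-378a-3p in that contrast and in SHR against WKY.

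Of the other X-linked miRNAs above the count filter, miR-871-3p and miR-883-3p were named after their values were seen. miR-871-3p was at 2.23, 5.00 and 0.152 CPM in SHR replicates 1 to 3, at 2.46, 4.93 and 0.336 in ZSHLF, and at 0.799, 0.287 and 0.194 in WKY. miR-883-3p was at 3.14, 5.00 and 0.304 in SHR, at 4.81, 3.21 and 0.336 in ZSHLF, and at 0.799, 0.287 and 0.875 in WKY. Some of these values lie at or under the detection floor of 3 reads in their library. The liver miRNA miR-122-5p was at 50.02 ± 72.8 CPM in ZSHLF and 10.4 ± 11.9 in WKY, a spread within the group larger than the mean.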
